A study of Mus musculus with 12 samples.

How the data were processed

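Gene expression was measured on Affymetrix mouse expression arrays in pancreatic islets, the clusters of hormone-secreting cells of the pancreas, from mice aged 12 weeks on standard chow. Per the labels, the mice were wild type (WT), carried a transgene for human islet amyloid polypeptide (hIAPP), lacked BACE2, or carried the transgene and lacked BACE2 (hIAPP/BACE2-KO), with 3 arrays per genotype and 12 in all. Human islet amyloid polypeptide is the peptide that forms islet amyloid, and BACE2 is an aspartyl protease of beta cells. The labels give the strain name B6;129P2-Bace2tm1Bdes/J for every group. RNA was taken up in Trizol and turned into biotinylated cRNA, per the labels' protocols. Each label speaks of a mouse, and nothing in the sources used here says whether islets of several mice were joined in an array, so the p-values measure the spread between these arrays.

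The deposited values are log2 expression levels, 1 per probe set and array, for 45141 probe sets. They were made with RMA (background correction, normalization between arrays and a summary over the probes of a set) and the affy package, per the submitters' processing notes; their versions are not given in the sources used here. The array medians ran from 4.22 to 4.35 and the highest values from 13.93 to 14.03, so the arrays shared 1 scale. No pair of arrays was a copy of another, since at most 2.22% of the values of an array equalled those of any other array. Array data hold no read depth, and the number of arrays limits the precision. Probe sets were named through the platform's annotation: 28898 had 1 gene symbol, 551 had several and were not named, and 15692, of which 104 are control sets, were not listed there. Entrez identifiers changed 0 symbols. No genome build is given in the sources used here, so no positions are printed. Which genes lie on a chromosome, and next to which, was read from a RefSeq table of assembly GRCm38.p6.

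Each gene was represented by the probe set with the highest mean over the 12 arrays among those with 1 symbol, which gave 17097 genes. Genes with a mean under the 25th percentile (log2 level 3.43) were left out, and 12825 were tested. A linear model with a mean per group was fitted to all 12 arrays at once with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a variance trend), so that the 4 groups shared an estimate of the spread. A gene was called at a two-sided Benjamini-Hochberg adjusted p under 0.05. The comparisons were hIAPP with WT, BACE2-KO with WT, hIAPP/BACE2-KO with each of the other 3 groups, the interaction of both changes, and each change averaged over the other. Differences are given in log2 units with the standard error (SE) of the fit, and levels as mean ± SD over 3 arrays. A simulated comparison of BACE2-KO with WT drew 12825 genes with independent normal noise and changed 50 genes at each size. The same steps recovered 32% of genes changed by 0.5 log2, 86% of those changed by 1, 100% of those changed by 2 and 98% of those changed by 3. That run called 165 genes, of which 7 were false. The real comparison called 16, and fewer calls make the adjusted threshold stricter, so these rates are not the power in the data.

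Of 40 lists of genes fixed before the data were examined (islet and other cell types, stress, signalling and metabolic pathways, and technical lists), 39 had at least 5 measured members. They were tested with limma's camera at a preset correlation between genes of 0.01, again at an adjusted p under 0.05 within a comparison. Camera with an estimated correlation and fry were the alternatives. Members past the gene test were counted over all genes tested and adjusted over the list alone. The genes named were also fixed by a rule before the data were examined. The rule took Bace2, Iapp, Ins1, Ins2 and Gcg, the 10 largest changes in each direction among called genes whose groups did not overlap (called genes in the interaction and averaged comparisons), up to 4 members of each list, and, where fewer than 5 genes were called, the 10 with the smallest p. Iapp and Ins1 have no probe set with a single symbol and were not analysed here.

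The alternatives were the filter on mean level, the choice of probe set, a further quantile normalization, median centring, the variance model, a fit of only the groups compared, the replicate number as a block, array weights, acinar or Y-linked transcripts as a covariate, a looser threshold, and each array left out in turn. A fit without the genes on chromosomes 8, 15 and 16 was added after seeing the data. Plots were drawn with matplotlib in Python.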

Results

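Islet transcript levels were measured in 4 genotypes at 12 weeks of age, with 3 arrays each: WT, hIAPP, BACE2-KO and hIAPP/BACE2-KO. The design compares islets with and without the human amyloid transgene, islets with and without BACE2, and each difference between both states of the other gene. It does not separate either change from genetic background bred along with it. All 12 arrays entered each fit, and 12825 genes were tested. The median difference over all genes lay between -0.03 and 0.03 in every comparison, so changes are given as fitted. If no gene differed, a share of about 0.05 of genes would still have an unadjusted p under 0.05. The share was 4.52% in hIAPP against WT, 4.44% in hIAPP/BACE2-KO against BACE2-KO and 2.4% in the interaction. It ran from 6.28% to 11.45% in the other comparisons. No gene list kept its call in any comparison when the correlation between genes was estimated from the arrays, nor with fry, and the p-value with an estimated correlation stands beside each list described.

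The targeted gene was read first. Bace2 had a level of 11.09 ± 0.16 (SD, n = 3) in WT, 11 ± 0.10 in hIAPP, 10.94 ± 0.08 in BACE2-KO and 10.85 ± 0.17 in hIAPP/BACE2-KO arrays. The difference between BACE2-KO and WT was -0.15 (SE 0.10, adjusted p = 0.941) on this probe set, and 0.04 and -0.18 on the others named Bace2. Whether these probes lie in the deleted part is not known here, so the transcript does not check the genotype, and every direction given for BACE2 loss rests on the labels. Ins2, an insulin gene, stood between 13.97 and 13.99 in the group means, at the top of the scale. In each array its value equalled the highest of that array, so a difference in its level is not resolved. Gcg, the glucagon gene, had means from 13.08 to 13.15. Neither passed the test in any comparison.

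The comparison of hIAPP with WT reads the transgene in islets that have BACE2. Sema5a, which encodes a transmembrane semaphorin known from axon guidance, rose from 3.52 ± 0.10 in WT to 8.19 ± 0.63 in hIAPP arrays, a difference of 4.67 (SE 0.32, adjusted p = 3.52e-05). Snhg18, a small nucleolar RNA host gene beside it on chromosome 15, rose by 2.14 (SE 0.23, adjusted p = 0.00393). The WT level of Sema5a lies near the filter level of 3.43, where low expression is not resolved, so the size of its rise is not resolved. These were the only 2 genes called, both higher, while 580 (4.52%) had an unadjusted p under 0.05, no more than without any change. The other Sema5a probe sets showed differences of 4.63, 0.94 and -0.03, and the mean of its probe sets 2.56. Among genes that did not pass, Lyz2, the lysozyme of macrophages, differed by 1.81 (SE 0.33, adjusted p = 0.568), and Apoe, an apolipoprotein found in amyloid deposits, by 2.05 (SE 0.41, adjusted p = 0.681).

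Macrophage and myeloid markers rose together in hIAPP arrays: 18 of 19 were higher, with a median of 0.44 (camera adjusted p = 6.38e-11; adjusted p = 0.489 with an estimated correlation). No member passed over all genes and 1 passed adjusted over the list alone. Ctss differed by 0.84, Tyrobp by 0.97 and Laptm5 by 0.73 (0.44 without hIAPP replicate 3). Lymphocyte markers rose too, with 10 of 11 higher and a median of 0.39 (adjusted p = 1.01e-05; adjusted p = 0.307 with an estimated correlation). None of them passed on its own by either count, and the median was 0.21 without hIAPP replicate 3, whose mean for these markers was 5.4 against 4.71 and 4.43 in the other hIAPP arrays, and 0.24 without WT replicate 3. Stellate cell and fibroblast markers rose, with 14 of 17 higher and a median of 0.28 (adjusted p = 0.00102; adjusted p = 0.579 with an estimated correlation), and 0 members passed by either count. Their median was 0.06 without hIAPP replicate 1, 0.14 and 0.48 without WT replicates 1 and 2, and 0.15 without WT replicate 3, where the call was lost (adjusted p = 0.054). Beta cell identity genes fell as a list, with 19 of 19 lower and a median of -0.24 (adjusted p = 4.71e-05; adjusted p = 0.579 with an estimated correlation), and 0 members passed by either count. Slc2a2, the glucose transporter of beta cells, differed by -0.68, the incretin receptor gene Gipr by -0.70 and the zinc transporter gene Slc30a8 by -0.37. Without hIAPP replicate 1 Slc2a2 stood at -0.37 and Slc30a8 at -0.23, and Gipr at -0.45 and -1.11 without hIAPP replicates 2 and 3. Without hIAPP replicate 1 the beta cell list lost its call (median -0.06, adjusted p = 0.2). Exocrine acinar markers had a median difference of -0.14 and endothelial markers of -0.11, and neither list was called. The remaining 8 called lists were higher, among them ribosomal proteins (24 of 24 higher, median 0.08, adjusted p = 5.29e-08; adjusted p = 0.579 with an estimated correlation) and transcripts known to vary between mouse strains (12 of 20 higher, median 0.06, adjusted p = 0.0215; adjusted p = 0.307 with an estimated correlation). The strain list lost its call without WT replicate 3 or hIAPP replicate 1, and its median was 0.04 and 0.03 without WT replicate 2 and hIAPP replicate 3. Without hIAPP replicate 2 only Sema5a was called, and a fit of only these 6 arrays did not call Snhg18.

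**Figure D1:**
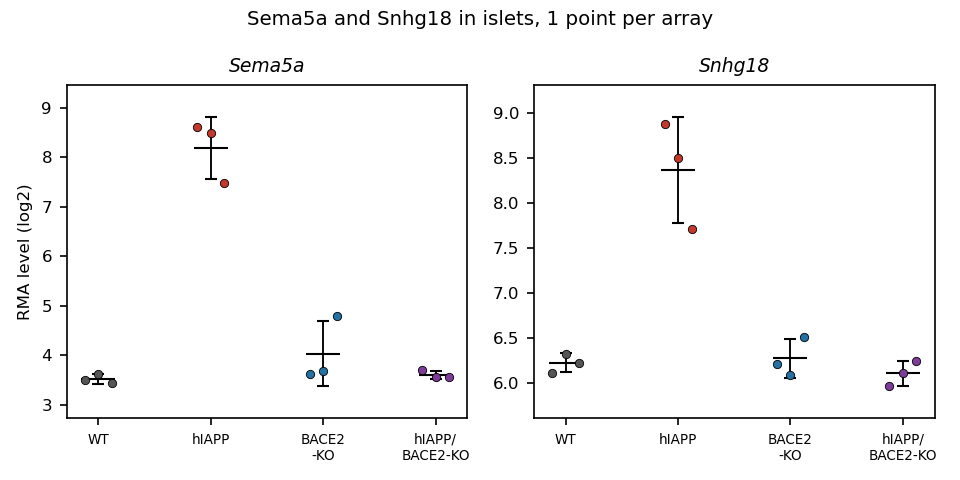
RMA levels (log2) of Sema5a and Snhg18 in each of the 12 arrays by genotype; each point is an array, and bars show the mean and SD of 3. The 3 hIAPP arrays lie above all 9 others for both genes, with a Sema5a mean of 8.19 against 3.52 in WT and 3.60 in hIAPP/BACE2-KO.

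BACE2-KO islets were compared with WT islets to see the effect of BACE2 loss without the transgene. The test called 16 genes, 9 higher and 7 lower, and 806 had an unadjusted p under 0.05. Ghrl, which encodes the hormone ghrelin, fell by 2.60 (SE 0.37, adjusted p = 0.0193), from 5.72 ± 0.89 to 3.12 ± 0.03. The latter is under the filter level of 3.43, so the size of the fall is not resolved. Over the settings the Ghrl difference ran from -2.902 to -1.972. Tex15, a gene of male meiosis, rose by 2.42 (SE 0.25, adjusted p = 0.0015), and Timmdc1, an assembly factor of mitochondrial complex I, rose by 1.53 (SE 0.12, adjusted p = 0.000292). Ppp1r3b, a glycogen-targeting phosphatase subunit, rose by 1.59, and Star, which carries cholesterol into mitochondria, rose by 1.36. Zcchc12 (1.05), Tmem35a (1.02), Fam81a (1), Pdgfrl (0.77) and Frg1 (0.52) were the other genes that rose. The genes that fell were the RNA-binding protein gene Rbm45 (-1.47), the nociceptin precursor gene Pnoc (-1.37), the melanocortin receptor accessory gene Mrap2 (-1.01), the replication helicase gene Mcm6 (-0.90), Hyi (-0.86) and the lipoxygenase gene Alox8 (-0.84), besides Ghrl. Tex15 in WT (3.35), and Mrap2 (3.31) and Alox8 (3.24) in BACE2-KO, also lay under the filter level, and Tmem35a in WT (3.47) near it, so the sizes of their differences are not resolved either. Tex15, Ppp1r3b, Star, Pdgfrl and Frg1 lie on chromosome 8, where 0.856 of 16 calls would be expected from its 686 tested genes (one-sided Fisher's exact test over genes, p = 0.00115; adjusted p = 0.023 over 20 chromosomes). The excess on chromosome 8 passed in hIAPP/BACE2-KO against WT, which shares the WT arrays (5 of 17, adjusted p = 0.0312), but not in hIAPP/BACE2-KO against hIAPP (4 of 13, adjusted p = 0.0788) or with BACE2 loss averaged (11 of 118, adjusted p = 0.51). These tests count the chromosome as a whole. The 5 genes lie in a span, set by themselves, of 59 tested genes, and the 4 called against hIAPP are among them. Timmdc1 lies on chromosome 16, as Bace2 does, but not among the 48 tested genes nearest to Bace2, of which 0 were called here.

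The PERK-ATF4 arm of the unfolded protein response, which raises amino acid synthesis and stress genes, rose as a list: 24 of 25 members were higher, with a median of 0.29 (adjusted p = 1.05e-09; adjusted p = 0.533 with an estimated correlation). No member passed over all genes, and 6 passed adjusted over the list alone. The median was 0.16 without WT replicate 1. Trib3 differed by 0.97, Psat1 by 0.85, Chac1 by 0.65 and Ddit3 by 0.49, but without WT replicate 1 Trib3 stood at 0.63, Psat1 at 0.43 and Chac1 at 0.42. Alpha cell markers rose, with 10 of 12 higher and a median of 0.28 (adjusted p = 0.00397; adjusted p = 0.533 with an estimated correlation), though without BACE2-KO replicate 3 the call was lost (adjusted p = 0.0758). Of these, 0 passed over all genes and 1 adjusted over the list alone. Oxidative stress genes rose, with 17 of 21 higher and Srxn1 at 0.34 and Nqo1 at 0.53 (adjusted p = 0.00397; adjusted p = 0.533 with an estimated correlation). Without BACE2-KO replicate 1 that list had a median of 0.06 and an adjusted p of 0.0943. Interferon-stimulated genes fell, with 22 of 28 lower and a median of -0.16 (adjusted p = 0.00547; adjusted p = 0.972 with an estimated correlation), but the call was lost without WT replicate 3 (median -0.13, adjusted p = 0.21). Without BACE2-KO replicate 2 the direction of this list turned, with a median of 0, and without BACE2-KO replicate 3 the median was -0.36. No member of the oxidative stress and interferon lists passed by either count. Endothelial markers fell, with 14 of 16 lower and a median of -0.16 (adjusted p = 0.00491; adjusted p = 0.693 with an estimated correlation), a call lost without WT replicate 3 (median -0.10) or BACE2-KO replicate 2 (median -0.03), and 0 members passed by either count. Of the other called lists, MHC class I genes were lower (9 of 10, adjusted p = 0.693 with an estimated correlation), and ribosomal proteins (23 of 24, 0.876), apoptosis and p53 targets (16 of 24, 0.533) and heat shock proteins (14 of 16, 0.533) were higher. Their calls were lost without BACE2-KO replicate 2 for MHC class I, BACE2-KO replicate 3 for ribosomal proteins and p53 targets, and WT replicate 1 or BACE2-KO replicate 1 for heat shock proteins. Exocrine acinar means per array ran from 7.58 to 10.17 in WT and from 8.82 to 10.17 in BACE2-KO, and that list was not called. The count of genes was 5, 6 and 9 without BACE2-KO replicates 1, 2 and 3, 7 and 8 without WT replicates 1 and 2, 9 without hIAPP replicate 2 and 10 without hIAPP/BACE2-KO replicate 3. Timmdc1, Tex15, Rbm45 and Pnoc were called in each of those fits, whereas Hyi was past the threshold in 8 of 23 settings, Alox8 in 10 of 23, and Star, Frg1 and Mcm6 in 10 of 24. Of the lists, 9 were called, but 14 without WT replicate 2.

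**Figure D2:**
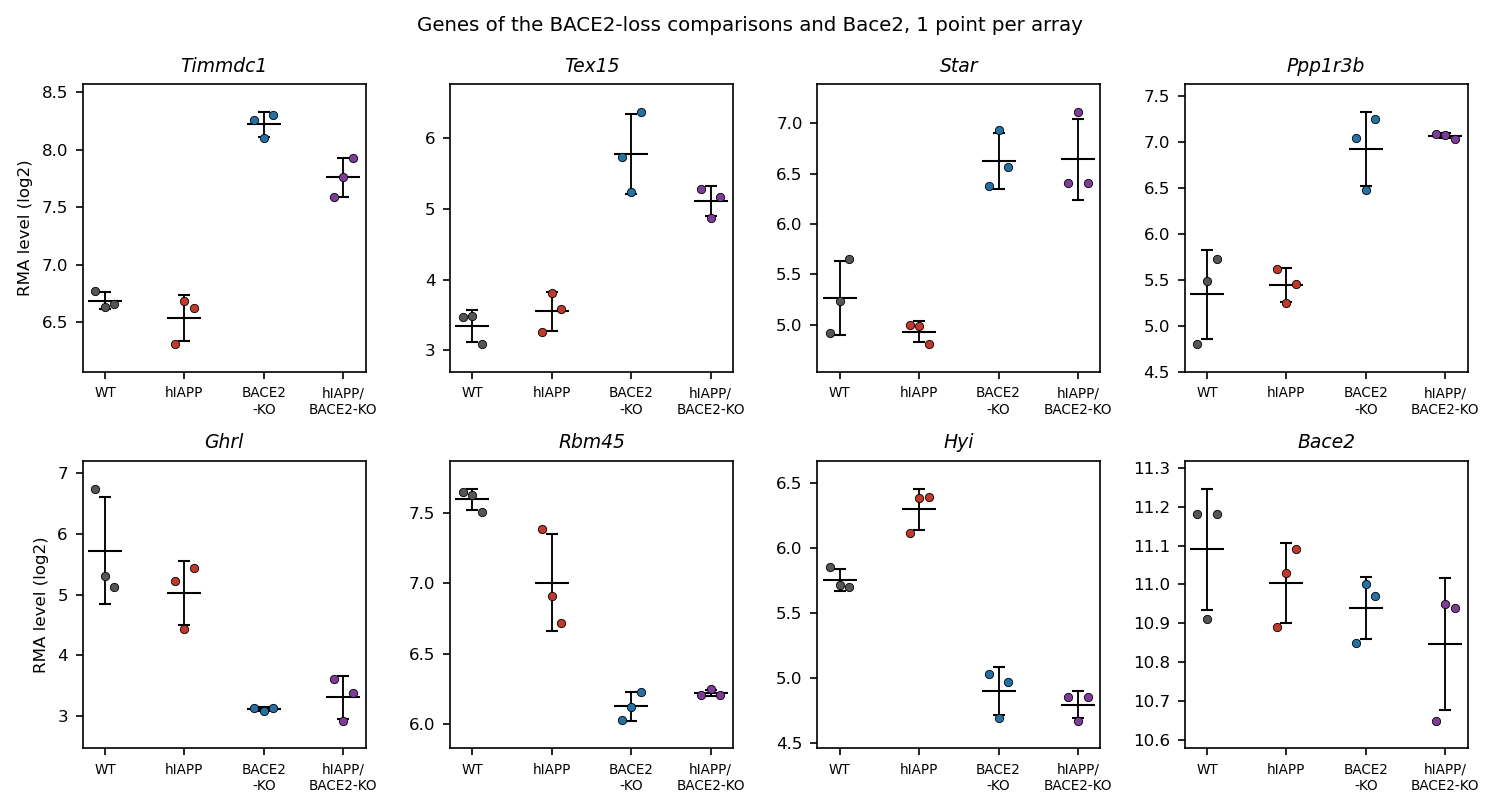
RMA levels (log2) of 7 genes called with BACE2 loss and of Bace2 itself in each of the 12 arrays by genotype; points are arrays, and bars show the mean and SD of 3. Timmdc1 lies at 6.69 and 6.54 on average in WT and hIAPP and at 8.22 and 7.76 in BACE2-KO and hIAPP/BACE2-KO, while the Bace2 means lie between 10.85 and 11.09.

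BACE2 loss in islets that carry the transgene was read from hIAPP/BACE2-KO against hIAPP arrays, which share no array with the comparison above. The test called 13 genes, 10 higher and 3 lower, and 1073 had an unadjusted p under 0.05. Sema5a fell by 4.59 (SE 0.32, adjusted p = 4.36e-05), to 3.60 ± 0.09, and Snhg18 fell by 2.26 (SE 0.23, adjusted p = 0.00109). That Sema5a level and the hIAPP level of Tex15 (3.55) lie near the filter level, so the sizes of the Sema5a fall and the Tex15 rise are not resolved. With the mean of its probe sets Sema5a fell by 2.56. Hyi fell by 1.5 (SE 0.14, adjusted p = 0.000757). Star (1.71), Ppp1r3b (1.63), Tex15 (1.55), Timmdc1 (1.22), Fam81a (1.12) and Pdgfrl (0.78) rose, as in BACE2-KO against WT. Fam163a (1.72), the amino acid transporter gene Slc7a3 (1.57), the kinase gene Stk35 (1.05) and the carnitine palmitoyltransferase gene Cpt1c (0.93) also rose. Those 6 genes and Hyi make 7 called in both BACE2-loss comparisons, all in the same direction, where 0.0162 would be expected of independent lists. The lists are not independent, since the fit shares each gene's spread between both comparisons, which alone raises such an overlap. Tex15, Ppp1r3b, Star and Pdgfrl also lie in the span on chromosome 8 named above. All 16 genes called in BACE2-KO against WT had the same sign here, 14 of them with an unadjusted p under 0.05, and of the 13 genes called here 11 had the same sign there, 10 of them with an unadjusted p under 0.05. Across genes, which are not independent replicates, the differences of both comparisons correlated with Pearson r = 0.401 and Spearman rho = 0.332.

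Macrophage markers fell in hIAPP/BACE2-KO against hIAPP arrays, with 16 of 19 lower and a median of -0.26 (adjusted p = 0.00153; adjusted p = 0.916 with an estimated correlation). Lyz2 differed by -1.34 (-0.87 without hIAPP/BACE2-KO replicate 1) and the complement gene C1qa by -0.45, no member passed over all genes, and 1 passed adjusted over the list alone. The hIAPP/BACE2-KO arrays differed widely in this list, with means of 5.55, 6.63 and 6.04, and without replicate 1 of that group the call was lost (median -0.02, adjusted p = 0.272). The median was -0.44 without replicate 2 of that group and -0.39 without hIAPP replicate 2. Lymphocyte markers fell, with 10 of 11 lower and a median of -0.48 (adjusted p = 0.0037; adjusted p = 0.881 with an estimated correlation), but the call was lost without hIAPP replicate 3 (median -0.13, adjusted p = 0.122), and the median was -0.29 without hIAPP/BACE2-KO replicate 1. The PERK-ATF4 arm rose with a median of 0.21 (21 of 25 higher, adjusted p = 0.0037; adjusted p = 0.916 with an estimated correlation), Trib3 by value at 0.85 and Psat1 at 0.72. Without hIAPP replicate 1 (median 0.08) or hIAPP/BACE2-KO replicate 2 it was not called. Heat shock proteins rose with a median of 0.12 (14 of 16 higher, adjusted p = 0.0414; adjusted p = 0.916 with an estimated correlation), a call lost without hIAPP replicate 1 or 3 or hIAPP/BACE2-KO replicate 2 (median 0.07) or 3. In the lymphocyte, PERK-ATF4 and heat shock lists 0 members passed by either count. The count of genes was 6 and 7 without hIAPP replicates 2 and 3, 5, 4 and 8 without hIAPP/BACE2-KO replicates 1, 2 and 3, and 3 in a fit of only these 6 arrays. Sema5a and Hyi were called in each of those fits, whereas Tex15 was past the threshold in 7 of 23 settings, Cpt1c in 9 of 24 and Fam163a in 10 of 24. Of the lists, 4 were called, but 11, 2 and 8 without hIAPP/BACE2-KO replicates 1, 2 and 3.

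**Figure D3:**
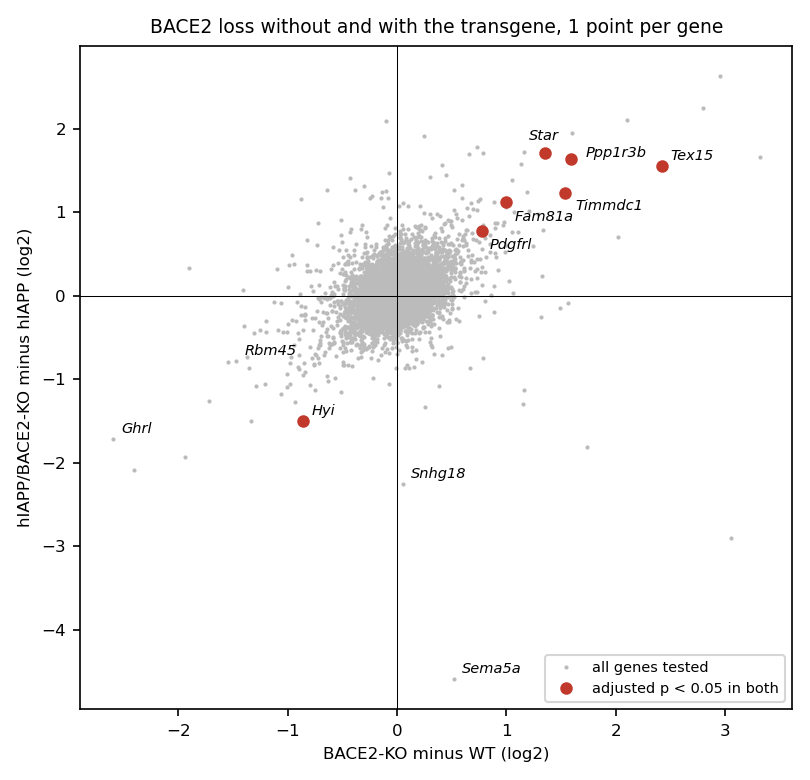
Difference between BACE2-KO and WT (x axis, log2) against the difference between hIAPP/BACE2-KO and hIAPP (y axis, log2), with a point for each of 12825 genes; larger points are the 7 genes called in both comparisons. Those genes lie in the quadrants of equal sign, and Sema5a lies at -4.59 on the y axis.

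The effect of the transgene in islets without BACE2 was read from hIAPP/BACE2-KO against BACE2-KO arrays. No gene was called by limma (smallest adjusted p = 0.9615), and every alternative fit without an array also called 0 genes. An unadjusted p under 0.05 was found for 569 genes (4.44%), no more than without any change. Sema5a, which rose with the transgene in islets with BACE2, differed by -0.43 here (SE 0.32), near the filter level, where low expression is not resolved. That value rests on BACE2-KO replicate 3, which had Sema5a at 4.79 against 3.62 and 3.69, and without it the difference was -0.06. Interferon-stimulated genes rose as a list, with 27 of 28 higher and a median of 0.40 (adjusted p = 2.91e-11; adjusted p = 0.442 with an estimated correlation), and Oas2 (1.13), Xaf1 (1.11) and Rtp4 (0.92) were among the members with the smallest p. Without BACE2-KO replicate 2 Xaf1 stood at 0.72 and Rtp4 at 0.52, and with the mean of their probe sets at 0.64 and 0.58. Stellate cell and fibroblast markers rose, with 17 of 17 higher and a median of 0.47 (adjusted p = 4.17e-09; adjusted p = 0.442 with an estimated correlation), including Pdgfrb at 0.66 and Mfap5 at 1.70 (0.81 without hIAPP/BACE2-KO replicate 2). In each of these lists 1 member passed adjusted over the list alone and none over all genes. Inflammatory and NF-kB genes (28 of 30 higher, median 0.41) and extracellular matrix genes (18 of 21 higher, median 0.37) rose as well, with adjusted p = 1.3e-07 and 2.55e-06, and adjusted p = 0.442 with an estimated correlation for each. Among them Il6 differed by 2.28 and Mmp2 by 1.47 (0.81 without hIAPP/BACE2-KO replicate 2), and 0 members passed by either count. These 4 lists kept their calls without each array in turn, but their medians moved. Without hIAPP/BACE2-KO replicate 2, which stood above the other arrays of its group in stellate (6.94 against 6.06 and 6.27) and matrix genes (6.90 against 6.10 and 6.13), the median was 0.30 for stellate, 0.22 for matrix and 0.22 for inflammatory genes. Without BACE2-KO replicate 2 it was 0.15 for interferon-stimulated and 0.18 for matrix genes, and without hIAPP/BACE2-KO replicate 1 it was 0.25 for inflammatory and 0.74 for stellate genes. Exocrine acinar markers fell, with 24 of 28 lower and a median of -0.45 (adjusted p = 0.0355; adjusted p = 0.695 with an estimated correlation), a call lost without BACE2-KO replicate 1 (median -0.08) or 2 or without hIAPP/BACE2-KO replicate 3 (median -0.16). Without BACE2-KO replicate 3 the median was -0.84. In all 17 lists were called, but 8 without BACE2-KO replicate 2 and 11 without hIAPP/BACE2-KO replicate 2.

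Islets with both changes were compared with WT islets. The test called 17 genes, 9 higher and 8 lower, and 1081 had an unadjusted p under 0.05. Of these, 12 stand above among the genes of BACE2-KO against WT, namely Tex15 (1.75), Ppp1r3b (1.73), Star (1.37), Timmdc1 (1.07), Fam81a (1.03), Zcchc12 (0.94), Frg1 (0.52), Mrap2 (-0.87), Hyi (-0.96), Pnoc (-1.24), Rbm45 (-1.37) and Ghrl (-2.41). Both comparisons use the WT arrays, which alone raises such an overlap, and the sizes for Tex15, Ghrl and Mrap2 (3.44 in hIAPP/BACE2-KO) are again not resolved. The other calls were Igfbp4, an insulin-like growth factor binding protein gene kept low in normal beta cells, which rose by 1.55 (SE 0.22, adjusted p = 0.0251), Rem2, a small GTPase gene, which rose by 0.85, and the vesicle GTPase gene Rab37 (-0.78), the mitochondrial transporter gene Abcb10 (-0.83) and Ush1c (-0.73), which fell. The PERK-ATF4 arm rose, with 23 of 25 higher, a median of 0.29 and Trib3 at 1.10 (adjusted p = 5.17e-09; adjusted p = 0.511 with an estimated correlation). No member passed over all genes, and 4 passed adjusted over the list alone. Stellate markers rose, with 16 of 17 higher and a median of 0.57 (adjusted p = 1.62e-06; adjusted p = 0.511 with an estimated correlation), and 1 member passed adjusted over the list alone and none over all genes. Their median was 0.36 without hIAPP/BACE2-KO replicate 2 and 0.38 without WT replicate 3. Apoptosis and p53 target genes rose, with 21 of 24 higher and a median of 0.23 (adjusted p = 1.94e-06; adjusted p = 0.159 with an estimated correlation). Of the members, 4 passed adjusted over the list alone and none over all genes, with Cdkn1a at 0.74 and Casp4 at 0.88 (0.54 without hIAPP/BACE2-KO replicate 1). Beta cell identity genes fell, with 15 of 19 lower and a median of -0.19 (adjusted p = 0.00778; adjusted p = 0.617 with an estimated correlation), a call lost without hIAPP/BACE2-KO replicate 1 (median -0.04) or WT replicate 3. Delta and PP cell markers fell, with 7 of 8 lower and a median of -0.19 (adjusted p = 0.00982; adjusted p = 0.571 with an estimated correlation), and lost their call without hIAPP/BACE2-KO replicate 2 (median -0.12, adjusted p = 0.075). That list holds Ghrl (-2.41) and was not tested without it, so its call may rest on this gene. Adjusted over the list alone 1 member of each was lower, and Ghrl was called over all genes. The other 9 called lists were higher. No gene was called without hIAPP/BACE2-KO replicate 2, and 3 and 4 were called without replicates 1 and 3 of that group. Without WT replicates 1, 2 and 3 the count was 6, 6 and 10, and without BACE2-KO replicate 3 it was 11. Abcb10 was past the threshold in 5 of 24 settings, Zcchc12 in 7, Star and Ush1c in 9 and Frg1 in 11.

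The interaction, the BACE2-loss difference with the transgene minus that without it, called Sema5a alone, at -5.11 (SE 0.45, adjusted p = 0.000722). An unadjusted p under 0.05 was found for 308 genes (2.4%), no more than without any change. With the mean of its probe sets the Sema5a interaction was -2.71, and its size is not resolved, since Sema5a lay near the filter level in WT and hIAPP/BACE2-KO. Snhg18 had an interaction of -2.31 (SE 0.33, adjusted p = 0.0705) and was not called. Interferon-stimulated genes had a positive interaction in 28 of 28 members with a median of 0.38 (adjusted p = 5.46e-06; adjusted p = 0.91 with an estimated correlation). Lymphocyte markers had a negative interaction in 10 of 11 with a median of -0.57 (adjusted p = 0.000124; adjusted p = 0.603 with an estimated correlation), and macrophage markers in 16 of 19 with a median of -0.31 (adjusted p = 0.000293; adjusted p = 0.91 with an estimated correlation). In these 3 lists 0 members passed by either count. The interferon list lost its call without BACE2-KO replicate 2 (median 0.22, adjusted p = 0.0955) and the macrophage list without hIAPP/BACE2-KO replicate 1 (median 0.01, adjusted p = 0.32). The interferon median was 0.68 and 0.23 without hIAPP replicates 1 and 3, the lymphocyte median -0.29 without hIAPP replicate 3, and the macrophage median -0.18 and -0.17 without BACE2-KO replicates 2 and 3 and -0.54 without hIAPP/BACE2-KO replicate 2. In all 8 lists were called, but 2 without BACE2-KO replicate 2 and 5 without hIAPP/BACE2-KO replicate 2, and 2 genes were called without hIAPP replicate 3.

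Averaging the BACE2-loss difference over both transgene states uses all 12 arrays and called 118 genes, 53 higher and 65 lower, while 1468 had an unadjusted p under 0.05. Of the genes with the largest changes, Tmem179 (2.10), Tex15 (1.99), Ccnb1ip1 (1.77), Ppp1r3b (1.61), the neuronal pentraxin gene Nptx2 (1.58), Star (1.53), Fam163a (1.44), Timmdc1 (1.38), Slc7a3 (1.35) and Tmem87a (1.25) rose. The water channel gene Aqp4 (-2.25), Ghrl (-2.16), Rpgrip1 (-1.94), Tnfrsf11b (-1.49), which encodes osteoprotegerin, Dcdc2a (-1.18), Hyi (-1.18), Rbm45 (-1.13) and the chemokine gene Ccl28 (-1.11) fell. Sema5a (-2.04) and Snhg18 (-1.11) were also called, through their high level in hIAPP arrays, and the size for Sema5a is not resolved, as above. Timmdc1 had the smallest adjusted p (1.72e-05, SE 0.09). Tex15 and Ccnb1ip1 in WT and Ghrl and Tnfrsf11b in BACE2-KO had means under the filter level, so the sizes of their differences are not resolved. With the mean of a gene's probe sets Rpgrip1 stood at -0.49, Sema5a at -1.20 and Aqp4 at -1.46, still called, whereas Ccl28 (-0.39, adjusted p = 0.477), Nptx2 (1.02, adjusted p = 0.105) and Me1 (0.18, adjusted p = 0.221) lost their calls. Rpgrip1 was not called with the robust variance model or without WT replicate 2. Among members of the lists, the cell cycle inhibitor gene Cdkn1a rose by 0.63 (adjusted p = 0.031), the beta cell ion channel gene Trpm5 by 0.61, the antioxidant gene Srxn1 by 0.36 and the lipogenic gene Me1 by 0.27, whereas Mcm6 (-0.71) and the dense-core vesicle gene Cadps2 (-0.54) fell. The PERK-ATF4 arm rose with a median of 0.23 (23 of 25 higher, adjusted p = 9.41e-08; adjusted p = 0.744 with an estimated correlation), and 7 members passed adjusted over the list alone and none over all genes. Heat shock genes rose with a median of 0.11 (15 of 16 higher, adjusted p = 0.00704; adjusted p = 0.744 with an estimated correlation). Of these, 0 passed over all genes and 2 adjusted over the list alone. Most settings ended the calls of Me1 (past the threshold in 7 of 23), Nptx2 (8), Srxn1, Tmem87a and Ccl28 (10) and Cadps2 (11). The list of reported BACE2 substrates was not called. The count of genes was 46 without WT replicate 1 or 2, 63 and 64 without hIAPP replicates 2 and 3, and 75 without hIAPP/BACE2-KO replicate 3. Of the lists, 5 were called, but 10 and 8 without WT replicates 2 and 3, 10 and 9 without BACE2-KO replicates 2 and 3, and 9 without hIAPP/BACE2-KO replicate 1.

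Averaging the transgene difference over both BACE2 states called only Sema5a, at 2.12 (SE 0.22, adjusted p = 0.00592), which the interaction above places in the islets with BACE2 and which was 1.20 with the mean of its probe sets, its size again not resolved, and 973 genes had an unadjusted p under 0.05. Stellate and fibroblast markers rose, with 16 of 17 higher and a median of 0.46 (adjusted p = 1.02e-08; adjusted p = 0.242 with an estimated correlation), with Pdgfrb at 0.51 and Postn at 0.86. Macrophage markers rose, with 16 of 19 higher and a median of 0.45 (adjusted p = 2.25e-07; adjusted p = 0.405 with an estimated correlation), with Lyz2 at 1.01 and Ctss at 0.72. In each of these lists 3 members passed adjusted over the list alone and none over all genes. Beta cell identity genes fell, with 17 of 19 lower and a median of -0.23 (adjusted p = 6.56e-05; adjusted p = 0.431 with an estimated correlation), and 0 members passed by either count. These 3 lists kept their calls without each array in turn, but without hIAPP/BACE2-KO replicate 2 the median was 0.26 for stellate and 0.28 for macrophage markers, and the beta cell median was -0.12 without hIAPP replicate 1 and -0.11 without hIAPP/BACE2-KO replicate 1. The strain-variable list was called here too (13 of 20 higher, median 0.11, adjusted p = 0.00388; adjusted p = 0.242 with an estimated correlation), with a median of 0.06 without WT replicate 3 or hIAPP replicate 1. Without hIAPP replicate 3 or hIAPP/BACE2-KO replicate 1 the test called 2 genes.

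**Figure D4:**
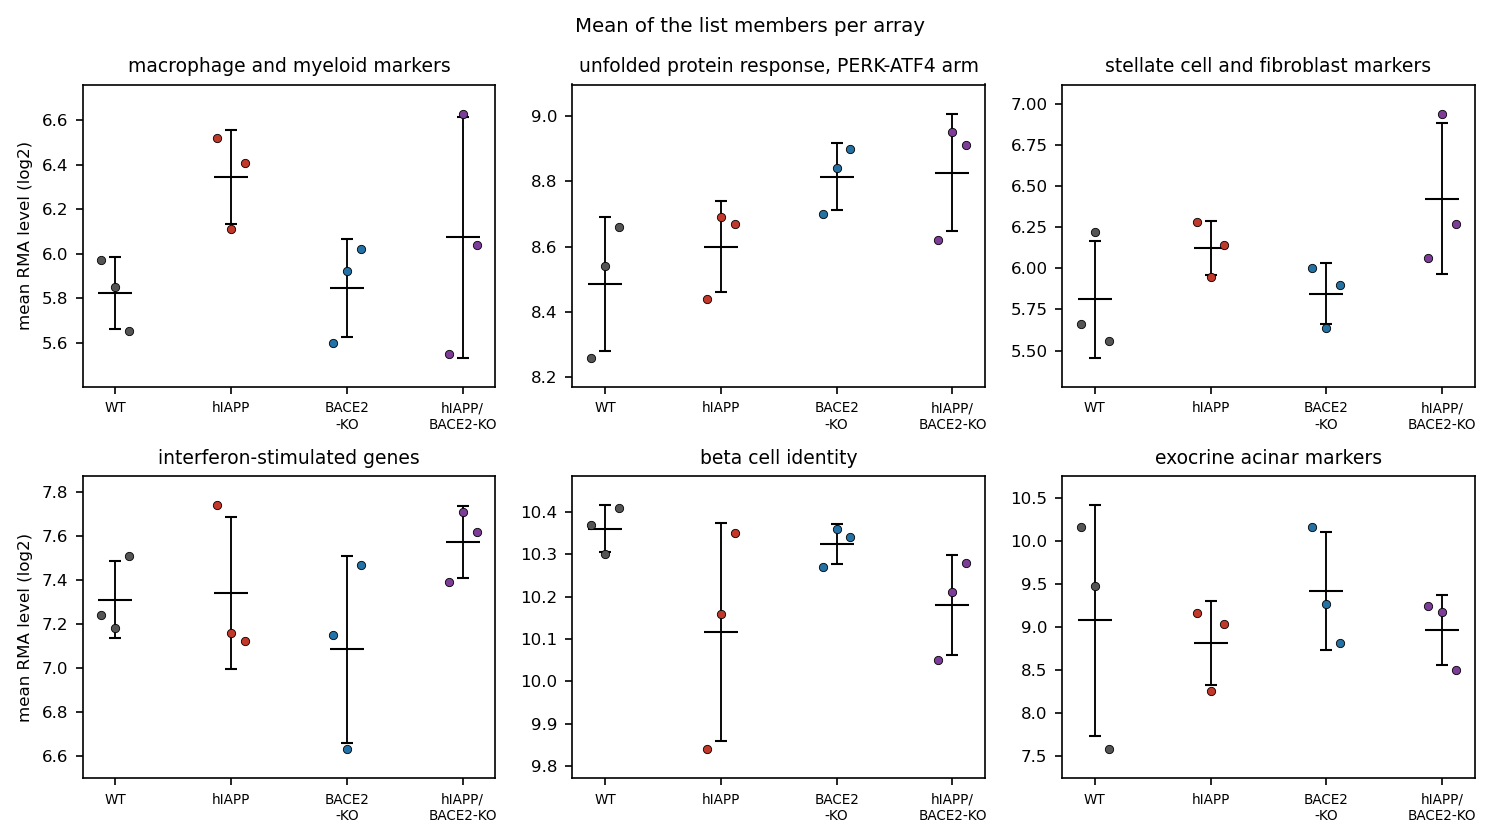
Mean RMA level (log2) of the measured members of 6 gene lists in each of the 12 arrays by genotype; points are arrays, and bars show the mean and SD of 3. The macrophage list has means of 5.82 in WT and 6.35 in hIAPP, the PERK-ATF4 list 8.49 in WT and 8.81 in BACE2-KO, and the exocrine acinar list spreads from 7.58 to 10.17 within WT.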

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

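The tests of the chromosome 8 span, of the acinar covariate on the averaged BACE2 calls, of Sema5a with Snhg18, of the macrophage list and of the strain-variable list were chosen after the results were seen, as were the chromosomes of the calls and the structure of the splits, and the splits, the genes around Bace2 and the acinar covariate on the hIAPP calls before.

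Results that depend on the other genotype stood out because they passed the test of the interaction. They were Sema5a (interaction -5.11) and the medians of the lymphocyte (-0.57), macrophage (-0.31), PERK-ATF4 (-0.13), ribosomal protein (-0.04), endothelial (0.19), inflammatory (0.33), interferon-stimulated (0.38) and extracellular matrix (0.40) lists. No list passed with an estimated correlation (lowest adjusted p = 0.603). With each array left out in turn, the call was lost in 8 of 12 fits for the inflammatory list, 6 for PERK-ATF4, 5 for ribosomal proteins, 4 for extracellular matrix, 2 for endothelial, 1 for macrophage, 1 for interferon-stimulated and 0 for lymphocyte genes. Leaving out 1 array moved every one of these medians by over 1.5 times. The endothelial median was 0.28 without WT replicate 1, 0.09 without hIAPP replicate 1, and 0.03 and 0.31 without BACE2-KO replicates 2 and 3, and the matrix median 0.23 without hIAPP/BACE2-KO replicate 2. The inflammatory median was 0.20 and 0.21 without hIAPP replicates 2 and 3, 0.22 without BACE2-KO replicate 3 and 0.19 without hIAPP/BACE2-KO replicate 2, and the interferon-stimulated one 0.68 and 0.23 without hIAPP replicates 1 and 3 and 0.22 without BACE2-KO replicate 2. The lymphocyte median was -0.29 without hIAPP replicate 3, and the macrophage median -0.18 and -0.17 without BACE2-KO replicates 2 and 3 and 0.01 and -0.54 without hIAPP/BACE2-KO replicates 1 and 2. PERK-ATF4 stood at 0.05 and -0.21 without WT replicates 1 and 3, -0.23, -0.06 and -0.07 without hIAPP replicates 1, 2 and 3, -0.05 without BACE2-KO replicate 3 and -0.01 without hIAPP/BACE2-KO replicate 1, and ribosomal proteins at -0.02 and -0.08 without hIAPP replicates 1 and 3 and -0.09 and -0.02 without hIAPP/BACE2-KO replicates 1 and 3. Probe sets without a gene name, which the gene test leaves out, also held calls. Of 9791 such sets, 1 was called in hIAPP against WT, 13 in BACE2-KO against WT, 13 in hIAPP/BACE2-KO against hIAPP, 15 in hIAPP/BACE2-KO against WT and 51 with BACE2 loss averaged.

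Each pairwise comparison has 10 splits of its 6 arrays, so no share under 0.05 can be had. The real split called 2 genes in hIAPP against WT (highest of the others 0), 16 in BACE2-KO against WT (0), 13 in hIAPP/BACE2-KO against hIAPP (7) and 17 in hIAPP/BACE2-KO against WT (0), and in each only 1 of the 10 splits, the real one, reached that count. In hIAPP/BACE2-KO against BACE2-KO all 10 splits reached the real count of 0, and the highest was 2. With BACE2 loss averaged, 1 of 100 splits, the real one, reached 118 genes and the highest of the others called 3, so a chance split does not account for it. With the transgene averaged, 24 of 100 splits called at least the 1 gene of the real split, and the highest called 3. Of the 23 others, 9 leave the labels within a BACE2 state whole and called Sema5a, so they hold the real difference, but 14 of the 83 that leave neither state whole called as many, and chance is not excluded for a count of 1 gene. For the interaction 16 of 100 splits called at least the real 1 gene, and the highest called 118, a structure of the samples, because exchanging the BACE2 labels within 1 transgene state turns the interaction into the averaged BACE2 comparison. Of the 15 others, 12 leave a transgene state whole, and of the 79 that leave neither whole 3 called as many. With the real split counted among them, as in the other shares, that share is 0.05 and not under it. These splits test a count of genes and not Sema5a, which passed in 22 of 22 settings of either comparison.

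The first pattern weighed was the set of genes changed with BACE2 loss, most of which do not lie in a passenger segment around Bace2, since 114 of the 118 averaged calls are on chromosomes other than 16. A segment of the donor strain could not be told apart from BACE2 loss for the rest: 0 of the 48 nearest tested genes were called in either BACE2-loss comparison, where 0.06 would be expected, so this decides nothing, and 1 (Tmprss2) was called with BACE2 loss averaged (Fisher's exact p = 0.359). Carry-over of exocrine tissue does not account for most of the calls, since 113 of the 118 averaged calls stayed past the threshold with the acinar level as a covariate. That covariate ended 4 of 16 calls in BACE2-KO against WT and 2 of 13 in hIAPP/BACE2-KO against hIAPP. A strain segment on chromosome 8, which is not the chromosome of Bace2, could not be told from BACE2 loss: the 52 uncalled genes in the span of the called ones had larger t statistics than random genes in BACE2-KO against WT (permutation p = 0.0053 over genes, which are not independent) but not in hIAPP/BACE2-KO against hIAPP (permutation p = 0.54). Tex15 lay at 4.87 or above in every array without BACE2 and at 3.81 or below in every array with it. Such a segment would have to follow the BACE2 labels in every array. BACE2 loss itself stays open beside such a segment.

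The second pattern was the rise of Sema5a and Snhg18 in hIAPP arrays. A local effect of the transgene insertion in every carrier does not account for it, as Sema5a stood 4.59 lower (-4.59) in hIAPP/BACE2-KO arrays, which carry it too per the labels. A single misbehaving probe set does not either, because another set showed 4.63, nor does exocrine carry-over, as 2 of the 2 genes stayed called with the acinar covariate. An altered chromosome segment could not be told apart: the 40 nearest tested genes gave permutation p = 0.053 over genes, and the largest difference among them was a lower level of Matn2 (-1.02). A difference in breeding line between the carriers may be the cause and stays open. So does an effect of the transgene that needs BACE2, which the design cannot tell from a difference in line.

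The third pattern was the rise of macrophage markers in hIAPP against WT. A lower share of endocrine cells would raise other non-endocrine markers too, endothelial ones included if endothelial cells were not lost along with endocrine cells. The macrophage median exceeded the endothelial one by 0.55 (permutation p = 4e-04 over genes, which are not independent). A lower share under that condition does not account for the whole rise. A joint loss of endocrine and endothelial cells is not tested by it. Stellate (0.28) and lymphocyte markers (0.39) were also higher at the median, unlike ductal (0.02) and acinar (-0.14) ones, so a gain of several non-endocrine cell types together stays open. Nor does a single array, as the lowest median was 0.34, without hIAPP replicate 1. More macrophages in the islets or more expression per macrophage stay open.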

How the results depend on the processing

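The fit without the genes on chromosomes 8, 15 and 16 was chosen after the results were seen, and all other settings before. No called gene turned its sign in any setting that measured it (0 in 205 pairs of setting and comparison). Many of these pairs could not turn a sign. No gene was called in hIAPP/BACE2-KO against BACE2-KO, and the filter, variance and threshold settings leave the fitted differences unchanged. Leaving out an array outside a pairwise comparison leaves its differences unchanged too. Without 1 array, camera gave 4 called lists the other direction: cholesterol synthesis in hIAPP against WT (WT replicate 1), interferon-stimulated genes in BACE2-KO against WT (BACE2-KO replicate 2), and the Reg family and ribosomal proteins in hIAPP/BACE2-KO against BACE2-KO (hIAPP/BACE2-KO replicates 2 and 1). The median changed sign in 7 of 87: PERK-ATF4, glycolysis and cholesterol synthesis in hIAPP against WT and PERK-ATF4 in the interaction (all WT replicate 1), endothelial markers (BACE2-KO replicate 2) and the Reg family (hIAPP/BACE2-KO replicate 2) in hIAPP/BACE2-KO against BACE2-KO, and macrophage markers in the interaction (hIAPP/BACE2-KO replicate 1). The cause of a changed count was not tested. The signal over background of the arrays limits the weakest genes, and with 3 arrays per group a single array carried many calls.

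No gene list was called with an estimated correlation (0) or with fry (0) in hIAPP against WT, BACE2-KO against WT, hIAPP/BACE2-KO against hIAPP, against BACE2-KO and against WT, the interaction, BACE2 loss averaged, or hIAPP averaged. With no filter on mean level 8 lists were called in hIAPP/BACE2-KO against hIAPP, with the acinar covariate 7, and with the mean of a gene's probe sets 9 with BACE2 loss averaged.

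A filter at the 50th percentile gave 1 gene in hIAPP against WT, 6 in BACE2-KO against WT, 7 in hIAPP/BACE2-KO against WT, 0 in the interaction and 0 with hIAPP averaged. Median centred arrays gave 23 in hIAPP/BACE2-KO against hIAPP, no variance trend 11 in hIAPP/BACE2-KO against WT and the robust model 2 in the interaction. A fit of only the groups compared gave 9 in BACE2-KO against WT, 3 in hIAPP/BACE2-KO against hIAPP and 4 in hIAPP/BACE2-KO against WT. Array weights gave 36 in BACE2-KO against WT and 34 in hIAPP/BACE2-KO against WT. The Y-linked covariate gave 1 in hIAPP against WT, 4 in BACE2-KO against WT, 5 in hIAPP/BACE2-KO against WT and 62 with BACE2 loss averaged. No array stood apart in sex-linked transcripts, with the Y-linked gene Uty between 6.82 and 7.43 and Xist between 3.23 and 3.91. That covariate therefore does not stand for a difference of sex between the groups. An adjusted p under 0.10 gave 27 in hIAPP/BACE2-KO against hIAPP, 2 in the interaction and 192 with BACE2 loss averaged. Without genes on chromosomes 8, 15 and 16, which removes called genes by construction, the counts were 0 in hIAPP against WT, 5, 3 and 9 in BACE2-KO against WT, hIAPP/BACE2-KO against hIAPP and against WT, 0 in the interaction and 0 with hIAPP averaged. Of the calls on other chromosomes 5 of 10, 3 of 6 and 2 of 11 were lost in those 3 comparisons, and 11 of 98 with BACE2 loss averaged.

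With the replicate number as a block 29 genes were called in hIAPP/BACE2-KO against hIAPP, 27 in hIAPP/BACE2-KO against WT and 205 with BACE2 loss averaged. The labels do not say that equal numbers pair samples. After removing group means, 5, 1 and 4 of 6 same-number pairs correlated above 0.1 for numbers 1, 2 and 3, and 8 of 12 arrays correlated best with their own number, a hint from the data and not from the design.

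With each array left out, genes called ranged from 1 to 3 in hIAPP against WT, 5 to 16 in BACE2-KO against WT, 4 to 17 in hIAPP/BACE2-KO against hIAPP, 0 to 0 against BACE2-KO, 0 to 18 against WT, 1 to 2 in the interaction, 46 to 108 with BACE2 loss averaged and 1 to 2 with hIAPP averaged. Lists called ranged, in the same order, from 10 to 16, 9 to 14, 2 to 11, 8 to 18, 10 to 18, 2 to 12, 4 to 10 and 17 to 20. The Bace2 difference between BACE2-KO and WT ranged from -0.24 to -0.105. Sema5a was called in all 23 settings of hIAPP against WT, and Timmdc1 and Rbm45 in all 24 of BACE2-KO against WT.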

Other observations

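With BACE2 loss averaged over the transgene, genes of prohormone processing and secretory granules moved in both directions: 3 of 19 were higher and 4 lower adjusted over the list alone, 1 was called over all genes (Cadps2, -0.54), and the list was not called (adjusted p = 0.738). Among 12 reported BACE2 substrates 2 were higher and 1 lower adjusted over the list alone, with Sez6l at -0.48, Fgfr1 at 0.36 and Plxna3 at 0.48, and none was called over all genes. Of the 39 lists, 14 were called in no comparison, among them the endoplasmic reticulum chaperones (smallest adjusted p = 0.327), oxidative phosphorylation (0.16), proliferation (0.0769) and amyloid processing and clearance (0.539).

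Rpgrip1 and Ccnb1ip1, with 13 tested genes between them on chromosome 14, differed among arrays without BACE2. In the 6 arrays of WT and hIAPP Rpgrip1 lay between 7.96 and 8.19, and in BACE2-KO arrays at 5.46, 5.51 and 7.35. Ccnb1ip1 lay at 5.48, 5.09 and 3.78 in the same BACE2-KO arrays. Pttg1 lay at 5.32 in WT replicate 3 and between 9.62 and 10.06 in the other arrays. Among probe sets without a gene name, the only one called with the transgene differed by 3.45 between hIAPP and WT (SE 0.38, adjusted p = 0.00399), and the one with the smallest p for BACE2 loss by 1.93 between BACE2-KO and WT (SE 0.16, adjusted p = 0.000159).

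The following hypotheses rest on tests chosen after the results were seen. Hypothesis: a mixed genetic background segregates within the groups, which is consistent with the spread of 20 strain-variable transcripts, whose median within-group SD of 0.288 against 0.172 lay at percentile 100 of 10000 random lists. The same list was called higher by camera in hIAPP against WT (adjusted p = 0.0215) and with hIAPP averaged (adjusted p = 0.00388), but not with an estimated correlation (adjusted p = 0.307 and 0.242). The hIAPP against WT call was lost without WT replicate 3 or hIAPP replicate 1. The list holds Pttg1, at 5.32 in WT replicate 3 against 9.62 to 10.06 in the other arrays. Camera tests a shared direction, whereas a strain difference can raise some transcripts and lower others, so these calls do not decide the question. Whether the background differs between mice with and without the transgene stays open. Genotyping strain markers in DNA of the same mice would test it. Hypothesis: some genes called with BACE2 loss, such as Tex15 and Ppp1r3b, may follow strain segments that differ between the lines and not BACE2. The span on chromosome 8 gave permutation p = 0.0053 in BACE2-KO against WT and 0.54 in hIAPP/BACE2-KO against hIAPP. Littermates with and without Bace2 from a fully backcrossed line would test it. Hypothesis: the Sema5a rise may belong to the line of the hIAPP mice and not to the transgene, given the difference of -4.59 between both carrier groups. A transgene effect that needs BACE2 would give the same difference, and amyloid was not measured in these data. Measuring Sema5a in hIAPP littermates of each BACE2 genotype would test the hypothesis.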
